A study of Arabidopsis thaliana with 12 samples.

How the data were processed

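RNA was measured by sequencing in fully expanded rosette leaves of Arabidopsis thaliana of 4 genotypes, wild type, sapx tapx, pgr5 and sapx tapx pgr5, with 3 libraries each. Per the labels, the plants were raised for 18 days in dim light of 40 to 60 µmol photons per square metre per second and then received 1500 µmol photons per square metre per second for 90 min. No library of leaves kept in dim light was analysed here, so the comparisons are between genotypes after the exposure and none of them measures a response to light. Per the labels' protocols, total RNA was purified on a column kit and made into libraries with the Illumina TruSeq RNA kit v2, which does not mark the strand. Reads from a gene and from an overlapping gene on the opposite strand can therefore not be told apart.

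The authors deposited 1 table per library, with no pooling of replicates. Per the file headers, each table gives raw read counts per gene (total and unique exon reads, gene reads, exon-exon reads and intron reads), together with RPKM and TPM values. The deposited counts are whole numbers with totals that differ between libraries. The deposited RPKM values were found to divide the exon reads by the exon length and by the sum of the gene reads over all genes of the table. The deposited TPM values were not used in any test. The genome build was TAIR10, per the submitters' processing notes, and coordinates are given as the deposited tables give them on that build. The aligner, the counting tool and the annotation release are not given in the sources used here. Each table lists 28642 genes, of which 28496 are nuclear and 146 mitochondrial. Gene symbols came from a reference table matched on the locus code, which named 28009 of the 28642 genes, and from the gene lists described next.

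Total exon reads per gene were used as counts. The libraries held 4916603 to 6828070 exon reads, so a gene with 100 reads in a library has a counting error of 10.0% and a floor of 3 reads corresponds to 0.439 to 0.610 CPM (reads of a gene per 1e6 reads). Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A floor of 3 reads over the 3 libraries of a group was used where a group had no read, and a ratio with its 95% counting interval was used where a group had 1 to 3 reads. Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filter on low counts (filterByExpr, which left 16350 genes), 1 quasi-likelihood fit over all 12 libraries and a contrast for each comparison. The comparisons were each mutant genotype with wild type, the triple mutant with each parent genotype, and the interaction, which asks whether the effect of pgr5 in the sapx tapx background differs from its effect in the wild type background. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 in the edgeR quasi-likelihood test. Every adjusted p of a single gene is of this kind, log2 fold changes carry the standard error that the test statistic implies, and levels are CPM with TMM scaling as mean ± SD over 3 libraries. Replicates are separate samples in the labels, but nothing in them says that they came from separate plants or cultures, so the p-values measure the spread between these samples, which may in part be technical. No pair of libraries of a group agreed within sampling noise, with chi-square values of 3.83 to 12.9 per degree of freedom.

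The fitting step was tested on simulated data for the comparison of the triple mutant with wild type. Counts for 16350 genes were drawn from the real means, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were taken only from those with an average level above 5 CPM. The fit recovered 69% of the genes with a 2-fold change and 96% of those with a 4-fold change. Recovery of genes below that level was not measured. There were 8 unchanged genes among 173 calls, 0 calls in the wrong direction, and 0 of 20 random gene lists called. Genes were drawn independently, so the 0 of 20 does not measure false calls of lists whose members vary together.

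Before the data were examined, the comparisons, the tests, 21 gene lists, the rule for named genes and most alternatives were fixed. The lists held antioxidant enzymes and ascorbate, hydrogen peroxide response and detoxification, singlet oxygen response, rapid stress transcription factors and touch genes, heat shock proteins and factors, endoplasmic reticulum chaperones, photoprotection and thylakoid repair, cyclic electron flow, light-harvesting and photosystem proteins, flavonoid and anthocyanin synthesis, jasmonate, salicylate and systemic defence, abscisic acid with drought and cold, glucosinolates, senescence and sugar starvation, the circadian clock, and markers of trichomes, guard cells, phloem, dividing cells and roots. They were written from general knowledge and had 442 members, of which 373 passed the filter. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 21 lists of a comparison. The directional test fry was run beside them.

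Named genes followed a rule of 4 parts. The first part names the 4 genes SAPX, TAPX, PGR5 and GL1. The second names the 8 largest rises and 8 largest falls of each comparison with wild type among called genes with a mean of at least 5 CPM and no overlap between the libraries of both groups, and the 5 largest each way for the triple mutant against its parents and for the interaction, the last without the overlap condition. The third names up to 4 called members of each list by size of change or, where none was called, up to 2 members with the highest level. The last allows a gene named once to be given in other comparisons. The rule took 142 genes in 345 pairs of gene and comparison, and not all of them are printed. Genes outside the rule are said to have been chosen after their values were seen.

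The alternatives fixed in advance were the relative log expression and upper-quartile scalings, no filter and a filter of 100 reads in 3 libraries, DESeq2 1.42.0, limma voom, a fit of the compared groups only, the replicate number as a block, a log2 fold change of at least 1, unique reads, leaving out mitochondrial genes, limma on log2(RPKM + 0.5), each of the 12 libraries left out in turn, and a candidate sequencing-run term read from sample-sheet numbers in the names of the deposited tables. Gene reads in place of exon reads, 1 surrogate variable from sva 3.50.0, the removal of a gene length trend by lowess with a span of 0.3, and the joint omission of 3 libraries were added after the data had been seen. Overlaps between comparisons that share libraries were set beside 20 simulated draws of unchanged groups. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.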

Results

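The transcriptomes of 4 Arabidopsis genotypes were compared after 90 min in strong light. SAPX and TAPX encode the stromal and thylakoid ascorbate peroxidases, chloroplast enzymes that remove hydrogen peroxide, and sapx tapx lacks both. PGR5 is needed for cyclic electron flow around photosystem I, and the triple mutant combines all 3 mutations. Each genotype was represented by 3 libraries of fully expanded rosette leaves. The libraries held 4916603 exon reads (sapx tapx replicate 2) to 6828070 (triple mutant replicate 3), and 16350 genes were tested in each comparison.

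SAPX (AT4G08390, chromosome 4, 5314905 to 5317456) stood at 214 ± 21.6 CPM (SD, n = 3) in wild type and 241 ± 7.99 CPM in pgr5, against 20.5 ± 4.72 CPM in sapx tapx and 20.8 ± 6.84 CPM in the triple mutant. TAPX (AT1G77490, chromosome 1, 29117542 to 29120215) stood at 170 ± 14.0, 200 ± 9.29, 18.4 ± 0.799 and 26.2 ± 1.59 CPM in the same order. The log2 fold changes of sapx tapx against wild type were -3.39 ± 0.21 for SAPX (adjusted p = 1.57e-05) and -3.21 ± 0.09 for TAPX (adjusted p = 5.22e-09), and in all 12 libraries the level of both genes went with the labelled genotype. TAPX was higher in the triple mutant than in sapx tapx by 0.51 ± 0.09 (adjusted p = 0.00537). PGR5 (AT2G05620, chromosome 2, 2081009 to 2081858) was at 243 ± 1.48 CPM in wild type, 278 ± 44.7 in sapx tapx, 241 ± 8.49 in pgr5 and 241 ± 36.6 in the triple mutant, with a log2 fold change of -0.01 ± 0.12 in pgr5 against wild type (adjusted p = 0.970). Its RNA level therefore does not check the pgr5 label. GL1 (AT3G27920), a trichome regulator, had 1 read in all 12 libraries and was not tested.

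**Figure D1:**
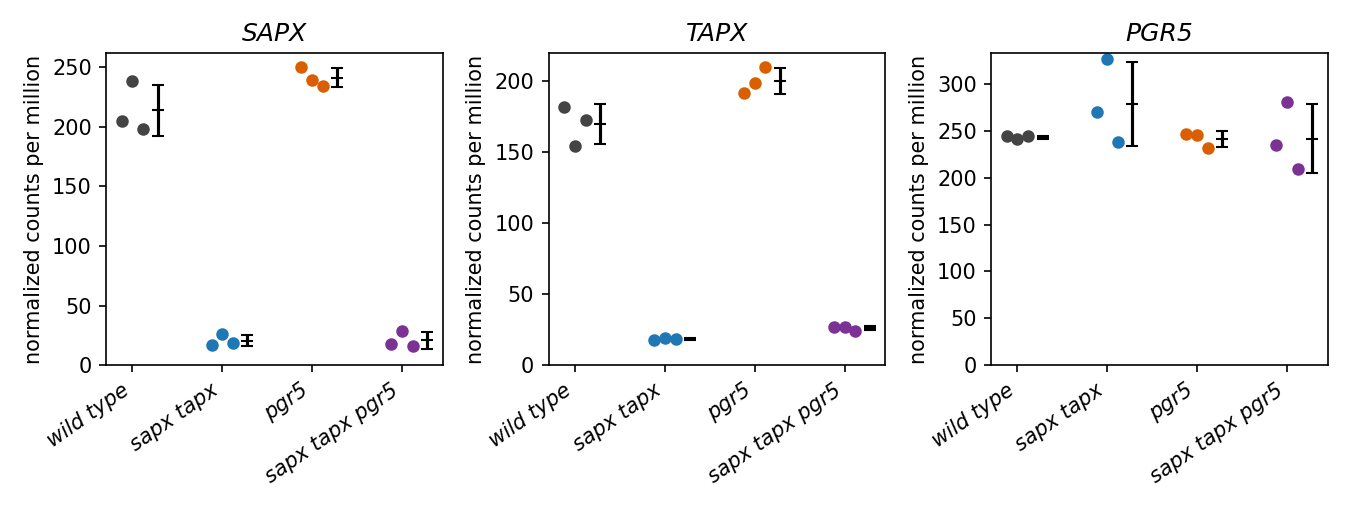
Normalized CPM of SAPX, TAPX and PGR5 in each of the 12 libraries (points) with the mean and SD of each genotype over 3 libraries (bar beside the points). SAPX and TAPX lie between 16.1 and 28.6 CPM in every library of sapx tapx and the triple mutant and between 155 and 250 CPM in every other library, and PGR5 lies between 209 and 327 CPM in all of them.

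Libraries of one genotype differed widely in rapid stress and touch genes. The mean log2 CPM of the 19 measured members of that list was 2.00 and 1.93 in wild type replicates 1 and 3 but 5.26 in wild type replicate 2. It was 5.78 and 5.34 in sapx tapx replicates 1 and 3 and 3.74 in replicate 2, and 5.35 and 5.18 in triple mutant replicates 1 and 3 and 3.04 in replicate 2. The 3 pgr5 libraries lay between 3.38 and 4.31. TCH4, a touch-induced cell wall enzyme, ranged from 11.7 CPM to 595 CPM within wild type. The first component of the differences within genotypes held 50.1% of their variance. Slopes were taken not on that component but on the deviation of the mean of the rapid stress list within each genotype. Jasmonate genes (median slope 0.72) and singlet oxygen genes (0.75) moved with that mean. Heat shock genes went both ways (median -0.05, from -0.33 to 0.63). The median of 0.89 for the rapid stress list itself is set largely by construction, and 4 of the 14 measured singlet oxygen genes are also in that list. No slope was taken for abscisic acid, glucosinolate or salicylate genes. Their mean log2 CPM was also highest in wild type replicate 2, at 5.89, 6.13 and 3.05. It was 4.84, 5.48 and 2.29 in replicate 1 and 4.92, 5.54 and 2.04 in replicate 3. In sapx tapx replicate 2 the glucosinolate and salicylate means were the lowest of the genotype, but the abscisic acid mean was the highest. Values for the 3 moving lists and for these lists in the comparisons that follow stand beside this spread.

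**Figure D2:**
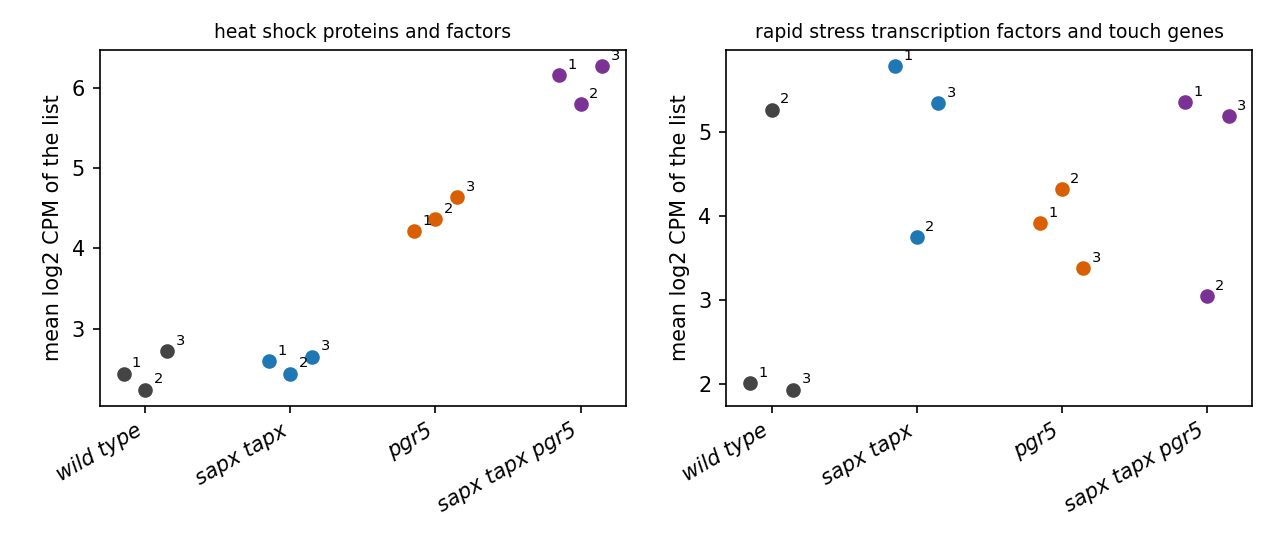
Mean log2 CPM of the 34 measured heat shock genes and of the 19 measured rapid stress and touch genes in each library (points, numbered by replicate) of the 4 genotypes. The heat shock score is 2.24 to 2.72 in wild type and sapx tapx, 4.22 to 4.64 in pgr5 and 5.79 to 6.27 in the triple mutant, while the rapid stress score spans 1.93 to 5.26 within wild type.

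The comparison of sapx tapx with wild type asks what the loss of both chloroplast ascorbate peroxidases changed. Apart from SAPX and TAPX, 4 genes passed the test. MRD1 (AT1G53480, chromosome 1, 19963047 to 19964712) fell from 19.95 ± 3.05 to 0.999 ± 0.607 CPM (log2 fold change -4.34 ± 0.36, adjusted p = 0.000304). QQS (AT3G30720, chromosome 3, 12349047 to 12349832), a regulator of carbon and nitrogen allocation, rose from 2.36 ± 1.07 to 15.3 ± 2.78 CPM (2.68 ± 0.27, adjusted p = 0.00151). The calmodulin-like gene CML23 rose by 1.13 ± 0.16 and AT3G11720 by 0.98 ± 0.13 on the log2 scale, each with an adjusted p of 0.0340. CML23 lost its call in 10 of 12 omissions of 1 library (highest adjusted p = 0.142, without sapx tapx replicate 2) and AT3G11720 in 8 (highest 0.185, without wild type replicate 1).

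None of the 34 heat shock genes and none of the 39 antioxidant genes passed the test, also when adjusted over the list alone, and their medians were -0.08 and 0.05. HSP70-4, a cytosolic chaperone, had a log2 fold change of -0.10 ± 0.29 and CAT2, a peroxisomal catalase, of 0.04 ± 0.11. Rapid stress genes had a median of 1.42 and singlet oxygen genes of 1.43, with 0 of 19 and 0 of 14 members past the test (1 and 0 adjusted over the list alone), examples being MYB44 at 0.67 ± 0.56 and WRKY33 at 1.43 ± 0.95. These medians were 2.99 and 3.35 without wild type replicate 2 and 0.85 and 0.91 without sapx tapx replicate 1, and that of the rapid stress genes was 0.93 without wild type replicate 1 or 3. The jasmonate list had a median of 0.11 with 0 of 29 past the test, LOX2, a jasmonate synthesis gene, being at -0.57 ± 0.38. This median was 1.56 without wild type replicate 2, -0.11 without wild type replicate 1 or sapx tapx replicate 1 and -0.10 without wild type replicate 3. Of the light-harvesting and photosystem genes 0 of 53 passed (3 rose adjusted over the list alone), with a median of 0.16 and RBCS1A at 0.21 ± 0.09. This median was 0.10 with the gene length trend removed, 0.09 without wild type replicate 2 and 0.08 without sapx tapx replicate 2. Over all genes the fold changes of this comparison fell with gene length (Spearman correlation -0.232). With camera at the preset correlation 10 of the 21 lists passed, 9 higher and 1, the guard cell markers, lower, and with an estimated correlation 0 did (adjusted p = 0.314 for the rapid stress, singlet oxygen, hydrogen peroxide, light-harvesting and abscisic acid lists, 0.293 for guard cells).

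In total 6 genes differed, 3 higher and 3 lower, in the edgeR quasi-likelihood test, and 1227 of 16350 genes had an unadjusted p under 0.05. The libraries of both groups did not overlap for 11.5% of genes, where chance gives 10%. With limma on RPKM 1 gene was higher and 3 were lower. DESeq2 called 56 genes (49 higher, 7 lower), the edgeR fit without wild type replicate 2 called 81, that without wild type replicate 2, sapx tapx replicate 2 and triple mutant replicate 2 together called 773, and a fit of these 6 libraries alone called 3.

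The comparison of pgr5 with wild type asks what the loss of PGR5 function changed in the same light. Heat shock genes led it. Of 34 measured members 22 rose and 0 fell (24 rose adjusted over the list alone), with a median log2 fold change of 2.04 (camera, adjusted p = 0.00267 with an estimated correlation). The heat stress factor HSFA2 (AT2G26150, chromosome 2, 11135682 to 11137396) rose from 4.45 ± 2.60 to 59.0 ± 3.21 CPM (3.71 ± 0.31, adjusted p = 8.21e-05). Among the small heat shock proteins HSP17.4 rose by 5.09 ± 0.63 (adjusted p = 0.00140) and HSP17.6-CII by 3.76 ± 0.34 (adjusted p = 0.000133). HSP17.6A had 282 reads against 3 in wild type, 90.6 times as many after scaling (95% counting interval 30.7 to 442, adjusted p = 0.00223). The ratio of HSP17.6C-CI was 52.1 (14.1 to 435, 108 reads against 2), and its call was lost without wild type replicate 3 (adjusted p = 0.0522), as was that of HSP23.6 (0.0542), whose log2 fold change was 3.63 ± 0.69. AT1G71000, a DnaJ-type chaperone gene, rose by 4.04 ± 0.43 (adjusted p = 0.000481).

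Photoprotection genes rose in pgr5, 8 of 19 with 0 falling (12 adjusted over the list alone), with a median of 0.30 and an adjusted p of 0.0993 with an estimated correlation. The early light-induced protein gene ELIP2 rose by 1.14 ± 0.13 (adjusted p = 0.000871), from 240 ± 36.9 to 530 ± 61.3 CPM, and the thylakoid protein kinase gene STN8 by 0.50 ± 0.09, a call lost without pgr5 replicate 2 (adjusted p = 0.0683) or 3 (0.0593). Of the antioxidant genes 4 of 39 rose and 0 fell (5 rose and 1 fell adjusted over the list alone), and the list as a whole did not pass camera (adjusted p = 0.175). They were the plastid glutathione peroxidase genes GPX7 (0.57 ± 0.10, lost without pgr5 replicate 3 at 0.0644) and GPX1 (0.36 ± 0.07, lost without wild type replicate 1, pgr5 replicate 1 or pgr5 replicate 3 at 0.0534 to 0.0568), the superoxide dismutase gene FSD1 (0.51 ± 0.09, lost without wild type replicate 1 or 3 or pgr5 replicate 1 at 0.0508 to 0.0530) and CAT2 (0.52 ± 0.11, lost in 5 omissions). APX1, the main cytosolic ascorbate peroxidase gene, had a log2 fold change of 0.11 ± 0.17. Of the hydrogen peroxide list 2 of 19 rose (2 adjusted over the list alone; adjusted p = 0.0993 with an estimated correlation), HSFA2 and the glucosyltransferase gene UGT74E2 (33 reads against 2, ratio 15.9, interval 4.07 to 137), the latter lost without wild type replicate 1 (adjusted p = 0.0530), wild type replicate 3 (0.0628) or pgr5 replicate 2 (0.0688).

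Endoplasmic reticulum chaperone genes fell in pgr5, 5 of 9 with 0 rising (6 adjusted over the list alone), with an adjusted p of 0.0998 with an estimated correlation. BIP1 fell by 0.70 ± 0.15, the calnexin gene CNX1 by 0.67 ± 0.14 and the calreticulin gene CRT1 by 0.54 ± 0.12 on the log2 scale. Each of these 3 calls was lost without wild type replicate 1, wild type replicate 3, pgr5 replicate 1 or pgr5 replicate 2, at adjusted p of 0.0597 to 0.118. The transcription factor gene GPRI1 (AT2G20570, chromosome 2, 8855358 to 8857756), also called GLK1 and known to promote photosynthesis genes, fell from 167 ± 45.4 to 37.1 ± 6.02 CPM (-2.17 ± 0.36, adjusted p = 0.00755). Of 53 light-harvesting and photosystem genes 2 fell and 1 rose (the same numbers adjusted over the list alone), and the list did not pass (adjusted p = 0.107). RBCS2B, a Rubisco small subunit gene with near-identical copies that can share its reads, fell by 1.53 ± 0.14 (adjusted p = 0.000133). UGT78D1, a flavonol glycosyltransferase gene, fell by 0.85 ± 0.12 (adjusted p = 0.00412) and was the only 1 of 19 flavonoid genes to pass (4 rose and 3 fell adjusted over the list alone; list adjusted p = 0.679).

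Markers of other cell types also differed between pgr5 and wild type. The phloem sucrose transporter gene SUC2 rose by 1.19 ± 0.11 (adjusted p = 0.000133), 1 of 2 phloem markers of 8 to rise (2 adjusted over the list alone; adjusted p = 0.198 with an estimated correlation). Of 14 trichome markers 3 fell and 0 rose (5 fell adjusted over the list alone; adjusted p = 0.198 with an estimated correlation). GL2, a trichome transcription factor gene, fell by 3.41 ± 0.43 (adjusted p = 0.00165). AT2G33850 (chromosome 2, 14321062 to 14322049) had 451 reads in wild type and 0 in pgr5 and was at least 156-fold lower. The pectin methylesterase gene PME61 fell by 2.22 ± 0.24 (adjusted p = 0.000588), AT1G78050 by 2.23 ± 0.32 (adjusted p = 0.00412) and AT2G16660 by 1.93 ± 0.32 (adjusted p = 0.00800). Root markers (0 of 3, 1 rose adjusted over the list alone), dividing cell markers (0 of 6, 1 fell), guard cell markers (0 of 10, 1 fell) and cyclic electron flow genes (0 of 12, 0) had no member past the test over all genes, and PGRL1A, the partner of PGR5, was at 0.12 ± 0.08.

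Of the remaining lists in pgr5, abscisic acid and cold genes had 3 of 23 members that rose (4 adjusted over the list alone; adjusted p = 0.307 with an estimated correlation), among them the cold factor genes CBF3 at 1.54 ± 0.36 and CBF2 at 2.09 ± 0.52, whose calls were lost in 6 and 9 of 12 omissions. Clock genes had 2 of 13 that rose (2 rose and 1 fell adjusted over the list alone; list adjusted p = 0.0781), salicylate genes 1 of 12 (PAD4, 0.75 ± 0.19, a call lost in 10 of 12 omissions with a highest adjusted p of 0.164) and senescence genes 0 of 5. DREB2A, a drought and heat factor gene, rose by 1.79 ± 0.34 (adjusted p = 0.0140, 0.0511 without pgr5 replicate 2) and was the only singlet oxygen gene of 14 to pass. Jasmonate genes had a median of -1.55 with 0 of 29 past the test (adjusted p = 0.492 with an estimated correlation, and 0.962 at the preset one without wild type replicate 2). Glucosinolate genes had a median of -0.33 with 0 of 20 past the test (adjusted p = 0.371 with an estimated correlation), and rapid stress genes a median of 0.01 with 0 of 19. The latter was -0.51 without pgr5 replicate 2 and 1.94 without wild type replicate 2, where the list passed camera at the preset correlation.

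In total 638 genes differed between pgr5 and wild type, 399 higher and 239 lower, and groups did not overlap for 25.8% of genes (10% by chance). The count fell to 287 without wild type replicate 1, 300 without wild type replicate 3, and 350, 210 and 247 without pgr5 replicates 1, 2 and 3. It was 337 when the compared groups alone were fitted, and with limma on RPKM 51.7% of calls were higher against 62.5%.

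The triple mutant was compared with wild type to show what the 3 mutations changed together. Of the 34 heat shock genes 27 rose and 0 fell (32 rose adjusted over the list alone), with a median log2 fold change of 3.95 (camera, adjusted p = 0.000285 with an estimated correlation). HSFA2 rose from 4.45 ± 2.60 to 153 ± 14.98 CPM (5.08 ± 0.32, adjusted p = 2.04e-06). HSP17.6B-CI (AT2G29500, chromosome 2, 12633091 to 12633805) rose from 2.89 ± 0.594 to 342 ± 74.2 CPM (6.88 ± 0.32, adjusted p = 3.28e-07). HSP17.8 rose by 5.84 ± 0.27 and HSP17.6-CII by 6.48 ± 0.35. HSP17.6A had 2233 reads against 3 in wild type (ratio 717, counting interval 245 to 3478) and HSP17.6C-CI 1065 against 2 (ratio 513, interval 142 to 4240). HSP17.4 rose by 7.69 ± 0.58, HSP23.6 by 6.73 ± 0.54 and AT1G71000 by 6.47 ± 0.38.

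Hydrogen peroxide response genes rose in the triple mutant, 12 of 19 with 0 falling (14 adjusted over the list alone), with a median of 0.94 (camera, adjusted p = 0.00129 with an estimated correlation). Of the 35 members of this list 19 passed the filter on low counts. A gene can pass it through 1 genotype alone, which favours members that are high there. HSFA2 is also in the heat shock list. The glutathione transferase gene GSTU24 had 143 reads against 1 in wild type (ratio 138, interval 24.3 to 5477) and UGT74E2 223 against 2 (ratio 107, interval 29.4 to 892). The cytochrome P450 gene CYP81D11 rose by 4.65 ± 0.83 (adjusted p = 0.00471). Of the antioxidant genes 10 of 39 rose and 0 fell (11 adjusted over the list alone; adjusted p = 0.101 with an estimated correlation). APX1 rose from 1935 ± 431 to 4925 ± 416 CPM (1.35 ± 0.17, adjusted p = 0.000430). The monodehydroascorbate reductase gene MDAR2 rose by 1.33 ± 0.21, the glutathione peroxidase gene GPX6 by 1.05 ± 0.11 and the dehydroascorbate reductase gene DHAR2 by 1.01 ± 0.19.

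Photoprotection genes rose in 8 of 19 cases and fell in 0 (13 rose adjusted over the list alone; adjusted p = 0.185 with an estimated correlation), with ELIP2 and SEP2 both at 1.09, with standard errors of 0.13 and 0.15, and the thylakoid protease gene FTSH8 at 0.87 ± 0.14. Endoplasmic reticulum chaperone genes split, with 6 of 9 falling and 1 rising (the same numbers adjusted over the list alone; adjusted p = 0.259 with an estimated correlation). CNX1 fell by 0.63 ± 0.14, a call lost without wild type replicate 3 (adjusted p = 0.0669) or triple mutant replicate 1 (0.0677), and the co-chaperone gene ERDJ3A rose by 1.56 ± 0.32. Of 19 flavonoid genes 4 fell and 1 rose (7 fell and 1 rose adjusted over the list alone; adjusted p = 0.259 with an estimated correlation), UGT78D1 by -0.69 ± 0.12 and 4CL3 by -0.60 ± 0.12. MYBL2, a repressor of anthocyanin synthesis, rose by 2.22 ± 0.56, a call lost without wild type replicate 1 or 3 or triple mutant replicate 1 or 3 (adjusted p of 0.0752 to 0.0922). Of the light-harvesting genes 2 of 53 rose and 2 fell (4 rose and 3 fell adjusted over the list alone; list adjusted p = 0.431), the ferredoxin genes FD1 (0.75 ± 0.10) and FD2 (0.47 ± 0.06) being higher and RBCS2B lower (-1.74 ± 0.14).

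Rapid stress genes had 3 of 19 members that rose (3 adjusted over the list alone; adjusted p = 0.594 with an estimated correlation). The zinc finger gene ZAT7 rose by 4.52 ± 0.84 and ZAT6 by 1.84 ± 0.35, and ZAT12 was at 2.06 ± 0.56, a call lost in 8 of 12 omissions. DREB2A rose by 2.76 ± 0.33 (adjusted p = 0.000302), 1 of 2 of the 14 singlet oxygen genes to rise (2 adjusted over the list alone; adjusted p = 0.594 with an estimated correlation). RVE1, a clock-related factor gene, rose by 3.05 ± 0.39 and was the only 1 of 13 clock genes to pass (1 adjusted over the list alone). Of 5 senescence genes 2 rose (2 adjusted over the list alone), DIN10 (3.48 ± 0.77, lost without wild type replicate 1 or 3 or triple mutant replicate 1 at 0.0553 to 0.0674) and the chlorophyll breakdown gene PAO (0.38 ± 0.07). Jasmonate (1 of 29 rose, 0 adjusted over the list alone), salicylate (1 of 12, 1), abscisic acid (1 of 23, 1), cyclic electron flow (1 of 12, 1) and root marker genes (1 of 3, 1) each had 1 member that rose, and glucosinolate genes had 0 of 20. None of these 5 calls held in every omission of 1 library, CORI3 being lost in 10 of 12, NDHM in 8, PAD4 and PYK10 in 4 each and COR47 in 3.

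Trichome markers fell in 5 of 14 cases and rose in 1 (5 fell and 2 rose adjusted over the list alone; adjusted p = 0.150 with an estimated correlation). GL2 had 3 reads in the triple mutant against 86 in wild type (29.8 times fewer, interval 9.85 to 147) and MYB23 was at -2.27 ± 0.47. SUC2 rose by 1.28 ± 0.11, 1 of 2 phloem markers of 8 to rise (3 adjusted over the list alone; adjusted p = 0.217 with an estimated correlation). The guard cell factor gene FAMA was at -0.53 ± 0.11, a call lost without triple mutant replicate 1 (0.0559), and was the only 1 of 10 guard cell markers to fall (2 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation). Of dividing cell markers 1 of 6 fell (1 adjusted over the list alone). AT2G33850 had 1 read against 451 in wild type (ratio 468, interval 83.6 to 18539). GPRI1 fell by 2.29 ± 0.36, AT1G78050 by 2.62 ± 0.33, the cytokinin response factor gene CRF3 by 2.27 ± 0.43 and G6PD3, a plastid glucose-6-phosphate dehydrogenase gene, by 1.86 ± 0.31.

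In total 1685 genes differed between the triple mutant and wild type, 1016 higher and 669 lower, and groups did not overlap for 27.2% of genes (10% by chance). The count was 1061 without wild type replicate 1, 879 without wild type replicate 3, 865 and 975 without triple mutant replicates 1 and 3, and 731 in a fit of the compared groups alone. The share of higher calls was 60.3%, but 50.03% with upper-quartile scaling and 42.2% with limma on RPKM. Fold changes fell with gene length in this comparison too (Spearman correlation -0.194).

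The triple mutant was next compared with sapx tapx, to ask what pgr5 changed in plants without the chloroplast ascorbate peroxidases. Heat shock genes rose again, 27 of 34 with 0 falling (27 adjusted over the list alone), with a median of 4.14 (4.14 also with 2 genes set to their lower bound; camera, adjusted p = 0.000211 with an estimated correlation). HSP17.6A (2233 reads against 0) was at least 698-fold higher and HSP17.6C-CI (1065 reads against 0) at least 333-fold higher. HSP23.6 had 590 reads against 3 (ratio 184, interval 62.7 to 896). HSP17.4 rose by 8.58 ± 0.64, HSP17.6B-CI by 6.67 ± 0.32 and HSFA2 by 5.03 ± 0.32 (adjusted p = 2.44e-06). Of the hydrogen peroxide genes 12 of 19 rose and 0 fell (13 adjusted over the list alone; adjusted p = 0.00269 with an estimated correlation), among them UGT74E2 (5.58 ± 0.50), GSTU24 (143 reads against 3, ratio 44.7, interval 14.98 to 219) and CYP81D11 (162 against 2, ratio 75.9, interval 20.7 to 632).

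Antioxidant genes rose in 6 of 39 cases and fell in 0 (7 adjusted over the list alone; adjusted p = 0.215 with an estimated correlation), led by APX1 at 1.22 ± 0.17, MDAR2 at 1.19 ± 0.21, GPX6 at 0.97 ± 0.11 and DHAR2 at 0.97 ± 0.19. DREB2A rose by 3.65 ± 0.36 and RVE1 by 4.04 ± 0.44, each the only member of its list to pass, of 14 singlet oxygen and 13 clock genes (1 singlet oxygen gene rose, and 1 clock gene rose and 3 fell, adjusted over the list alone). Of 19 photoprotection genes 6 rose and 0 fell (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.340 with an estimated correlation), with ELIP2 among them (adjusted p = 0.000103). SUC2 rose by 1.16 ± 0.11, 1 of 2 phloem markers of 8 to rise (4 adjusted over the list alone; adjusted p = 0.290 with an estimated correlation). Trichome markers fell in 4 of 14 cases and rose in 1 (4 fell and 2 rose adjusted over the list alone; adjusted p = 0.290 with an estimated correlation), GL2 with 3 reads against 51 (18.1 times fewer, interval 5.87 to 90.9), MYB23 by -2.45 ± 0.47 and TTG2 by -1.95 ± 0.38, against TTG1 at 1.14 ± 0.19. RBCS2B fell by 1.75 ± 0.14 and kept its call in every omission, as did AT2G33850 (1 read against 204, ratio 218, interval 38.6 to 8642), AT1G78050 (-2.61 ± 0.33), CRF3 (-2.54 ± 0.42) and the repressor gene ERF4 (-2.45 ± 0.40). MRD1 was higher by 3.41 ± 0.38 and QQS lower by 2.33 on the log2 scale (-2.33 ± 0.26). The endoplasmic reticulum, flavonoid and light-harvesting lists each passed camera as lower at the preset correlation (adjusted p = 0.340, 0.584 and 0.794 with an estimated correlation).

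In total 1293 genes differed, 782 higher and 511 lower, and groups did not overlap for 24.3% of genes (10% by chance). The count was 851 and 747 without sapx tapx replicates 1 and 3, and 790 and 746 without triple mutant replicates 1 and 3.

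The comparison of the triple mutant with pgr5 asks what sapx tapx changed in plants without PGR5 function. Reads that cross exon junctions made up 42.0% of exon reads in the triple mutant and 43.6% in pgr5. A difference in library preparation and an effect of genotype can therefore not be told apart, as described below. The same holds for sapx tapx and the triple mutant against wild type. Over all genes the fold changes fell with gene length (Spearman correlation -0.210). Heat shock genes rose further, 24 of 34 with 0 falling (28 adjusted over the list alone), with a median of 1.56 (camera, adjusted p = 0.00140 with an estimated correlation). HSP17.6B-CI rose from 30.9 ± 10.6 to 342 ± 74.2 CPM (3.47 ± 0.26, adjusted p = 4.78e-05), HSP17.6C-CI by 3.30 ± 0.41, HSP23.6 by 3.10 ± 0.36 and HSP17.6A by 2.99 ± 0.38. Hydrogen peroxide genes rose in 8 of 19 cases and fell in 0 (12 adjusted over the list alone; adjusted p = 0.00145 with an estimated correlation). GSTU24 had 143 reads against 1 (ratio 143, interval 25.2 to 5682), the cytochrome P450 gene CYP81D8 rose by 2.90 ± 0.37 and UGT74E2 by 2.74 ± 0.35. UGT74F2, a salicylate glucosyltransferase gene, rose by 3.07 ± 0.34 (adjusted p = 0.000647).

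Antioxidant genes rose in 4 of 39 cases and fell in 0 (5 adjusted over the list alone; adjusted p = 0.141 with an estimated correlation). MDAR2 rose by 1.73 ± 0.22 (adjusted p = 0.00154) and APX1 by 1.24 ± 0.17 (adjusted p = 0.00241). GPX6 at 0.64 ± 0.10 lost its call without pgr5 replicate 2 (0.0593) or 3 (0.0660) and DHAR2 at 0.84 ± 0.19 in 9 of 12 omissions. Flavonoid genes fell in 4 of 19 cases and rose in 0 (8 fell adjusted over the list alone; adjusted p = 0.163 with an estimated correlation). PAL1, the entry enzyme gene of phenylpropanoid synthesis, fell from 657 ± 42.9 to 429 ± 27.0 CPM (-0.61 ± 0.08, adjusted p = 0.00229). The flavonol synthase gene FLS1 fell by 0.72 ± 0.12, a call lost without triple mutant replicate 1 (0.0520), and the chalcone synthase gene CHS by 0.60 ± 0.12, lost without pgr5 replicate 1 or 3 or triple mutant replicate 1 or 2 (0.0747 to 0.125). Of the other lists, light-harvesting genes (2 of 53 rose, 4 adjusted over the list alone), jasmonate genes (1 of 29, 1), and rapid stress genes (1 of 19, 1) passed camera as higher at the preset correlation only (adjusted p = 0.651, 0.560 and 0.808 with an estimated correlation), as did glucosinolate genes with 0 of 20 (0.560). No trichome, phloem, guard cell, dividing cell or root marker passed, SUC2 being at 0.09 ± 0.10.

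In total 252 genes differed, 220 higher and 32 lower, and groups did not overlap for 20.5% of genes (10% by chance). The count was 127, 115 and 112 without pgr5 replicates 1, 2 and 3, and 116 and 154 without triple mutant replicates 1 and 3. The share of higher calls was 87.3%, and 77.2% with limma on RPKM.

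The interaction asks whether the effect of pgr5 differed between the sapx tapx and wild type backgrounds on the log2 scale. Heat shock genes had a median interaction of 1.77, with 5 of 34 higher and 0 lower (24 adjusted over the list alone; camera, adjusted p = 0.0101 with an estimated correlation). HSP17.6B-CI had an interaction of 3.25 ± 0.46 (adjusted p = 0.0138), the co-chaperone gene BAG6 of 3.14 ± 0.52 (adjusted p = 0.0481), HSP17.8 of 2.45 ± 0.37 (adjusted p = 0.0196) and the chaperone gene HSP90.1 of 2.26 ± 0.37 (adjusted p = 0.0462). Leaving out 1 library ended the call of HSP17.6B-CI for wild type replicate 1 (0.0741), sapx tapx replicate 3 (0.0608) and pgr5 replicate 2 (0.0545), that of HSP17.8 in 8 of 12 omissions, and those of BAG6 and HSP90.1 in 10. MRD1, which stood at 19.95, 0.999, 17.62 and 10.4 CPM in wild type, sapx tapx, pgr5 and the triple mutant, had an interaction of 3.59 ± 0.46 (adjusted p = 0.00993), and CML23, at 9.96, 21.9, 16.1 and 10.3 CPM, of -1.77 ± 0.22 (adjusted p = 0.00993). Both kept their calls in all 12 omissions. AT4G01870 had an interaction of 2.72 ± 0.37 (lost without pgr5 replicate 1 at 0.0549 or 2 at 0.0545) and the ubiquitin ligase gene RDUF1 of -2.16 ± 0.30 (lost without sapx tapx replicate 3 at 0.0593 or pgr5 replicate 1 at 0.0549). APX1 was at 1.12 ± 0.23 and did not pass (adjusted p = 0.143).

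In total 23 genes had an interaction, 21 higher and 2 lower, and 1151 had an unadjusted p under 0.05. The count was 10 without pgr5 replicate 2, 13 without pgr5 replicate 1 or sapx tapx replicate 3, and 61 without wild type replicate 2, and DESeq2 called 99 and limma on RPKM 42. The hydrogen peroxide list (0 of 19 past the test, 6 higher adjusted over the list alone) and the jasmonate list (0 of 29, 0) passed camera as higher at the preset correlation but not with an estimated one (adjusted p = 0.159 and 0.700). The direction of the jasmonate list turned without wild type replicate 2 (median -0.18 against 0.87). With replicate 2 of wild type, sapx tapx and the triple mutant all left out it passed as lower (median -0.23, adjusted p = 5.8e-05). The abscisic acid (0 of 23, 3 lower adjusted over the list alone), flavonoid (0 of 19, 3 lower), rapid stress (0 of 19, 0) and cyclic electron flow lists (0 of 12, 0) passed as lower at the preset correlation only (adjusted p = 0.448, 0.448, 0.610 and 0.610 with an estimated correlation).

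The pgr5 genotype was compared in both backgrounds on libraries that are not shared. A line background or a segment around PGR5 that both pgr5 genotypes may carry would also give shared calls. The overlap therefore does not tell these apart from an effect of pgr5 itself, as described below for trichome genes. Of the genes called in pgr5 against wild type and in the triple mutant against sapx tapx, 241 were higher in both, where independent lists would share 19.1, and 113 were lower in both, where independent lists would share 7.47. Only 3 genes were called in opposite directions. HSFA2, ELIP2 and SUC2 were among the genes higher in both comparisons and GL2, AT1G78050 and RBCS2B among those lower in both. Across the 16350 genes, which are not independent replicates, the log2 fold changes correlated at 0.589 (covariance 0.161). Among comparisons that share the wild type libraries, pgr5 and the triple mutant had 279 genes higher in both (24.8 for independent lists), 158 lower in both (9.78) and 0 opposite. Simulated unchanged groups gave 0 shared calls, a correlation of 0.502 and a covariance of 0.0457, beside 0.706 and 0.193 as observed. In these draws every library, wild type included, was drawn anew from the wild type means, with genes independent of each other. The spread that the real wild type libraries share across rapid stress genes is therefore absent from them. The 3 wild type libraries are too few to split, so part of the excess may come from the shared controls. For sapx tapx and the triple mutant the correlation was 0.276 and the covariance 0.0518 (simulated 0.495 and 0.0454), and 4 genes were called in both in the same direction, of which SAPX and TAPX are mutated in both genotypes and MRD1 and AT3G11720 are the others. For sapx tapx and pgr5 the correlation was 0.208 and the covariance 0.0319 (simulated 0.4997 and 0.0459), and 1 gene, CML23, was called in both. The effect of sapx tapx in the wild type and pgr5 backgrounds, again on separate libraries, correlated at 0.149. In both comparisons fold changes fell with gene length (Spearman correlation -0.232 and -0.210). How much of the 0.149 comes from that shared trend was not tested. Called in both in the same direction were 3 genes, SAPX, TAPX and AT3G11720, so that only 1 of them is not a mutated gene.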

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

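The depth test and the splits and relabellings of libraries were written before their results were seen. The interaction test and the tests of gene lists were likewise fixed in advance. All other tests in this part were chosen only after the patterns were seen, so they are tests, not predictions. A test of the interaction itself picked out 23 genes for which the effect of pgr5 differed between the sapx tapx and wild type backgrounds. The largest among named genes were MRD1 at 3.59, HSP17.6B-CI at 3.25, BAG6 at 3.14, AT4G01870 at 2.72, HSP17.8 at 2.45, HSP90.1 at 2.26, RDUF1 at -2.16 and CML23 at -1.77 on the log2 scale. Relabelling the 12 libraries gave as many interaction calls in 5 of 100 ways, the real labels included, with up to 440, so a chance arrangement of libraries is not excluded for the count of 23. For the comparisons of 3 with 3 libraries the 10 possible splits are too few for a verdict. The real labels gave 638, 1293 and 252 calls for pgr5 against wild type, the triple mutant against sapx tapx and the triple mutant against pgr5, where the highest other split gave 0 each time, and 1 split of 10, the real one, reached the count. For the triple mutant against wild type 1 of 10 splits reached 1685. The highest other, 931, came from exchanging wild type replicate 2 with triple mutant replicate 2. For sapx tapx against wild type 2 of 10 splits reached the 6 calls, and exchanging wild type replicate 2 with sapx tapx replicate 2 gave 308. Both exchanges point to structure among the compared libraries other than genotype.

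The pattern weighed first was that libraries of one genotype differed in rapid stress and touch genes. A difference in read depth was excluded, since thinning all libraries to equal depth left 0.976 of the spread. Another mix of cell types remains open, since the largest median slope among 5 marker lists, that of trichomes, was 0.113 of that of the rapid stress genes but members of each list went both ways. Harvest at another time of day remains open too, as clock genes had a median absolute slope (0.108) above that of 98.7% of matched random lists, and those of trichome (0.140) and root markers (0.115), not set beside random lists, were larger. A swap of labels between wild type replicate 2 and a library of either APX-deficient genotype is excluded by SAPX and TAPX, and touching or wounding before harvest was not tested.

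The share of exon reads that cross exon junctions, a measure that no comparison of the report tests, differed between genotypes. Such reads made up 41.8 ± 0.403% of exon reads in the 6 libraries of sapx tapx and the triple mutant and 43.6 ± 0.152% in the other 6, a difference of -1.85 percentage points (exact permutation p = 0.00216 over 924 splits, the smallest possible). A difference in library preparation or sequencing and an effect of genotype cannot be told apart, since these 6 libraries share both APX mutations, and the 65.0% of spliced genes with a lower share in the triple mutant than in pgr5 would follow from either. More unspliced RNA did not show in the intron share, which was 1.28 ± 0.145% in these 6 libraries and 1.42 ± 0.146% in the others. This difference of -0.133 points lies within the spread (exact permutation p = 0.145), so a small rise is not excluded. A gene length trend was excluded as the whole cause of the calls, since 87.3% of those of the triple mutant against pgr5 remained with the trend removed.

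Of 14 trichome genes 3 fell in pgr5 against wild type, and 4 fell and 1 (TTG1) rose in the triple mutant against sapx tapx, with an adjusted p of the list of 0.198 and 0.290 with an estimated correlation. A background without trichomes shared by both and an effect of pgr5 itself cannot be told apart. Either would lower the same genes in both comparisons. All 3 of the trichome genes that fell in pgr5 (GL2, MYB23 and ZFP8) also fell in the triple mutant against sapx tapx. In pgr5 against wild type MYB23 lost its call in 3 and ZFP8 in 9 of 12 omissions. The labels do not state a glabrous1 background, in which pgr5 lines have often been kept. Variants on the segment around PGR5 remain open, with an odds ratio of 1.87 (95% interval 1.00 to 3.25, Fisher's exact test p = 0.0311, adjusted p = 0.0779) for a call within 1 Mb in the triple mutant against sapx tapx and 1.19 (p = 0.618, Fisher's exact test) in pgr5 against wild type. Of the calls near PGR5 7 of 15 were lower in the triple mutant against sapx tapx and 4 of 5 in pgr5 against wild type. The odds ratio was 1.97 (1.14 to 3.23, Fisher's exact test p = 0.0103, adjusted p = 0.0517) in the triple mutant against wild type, and it was 1.82 (0.366 to 5.52, Fisher's exact test p = 0.237) in the triple mutant against pgr5, where both groups carry the pgr5 segment.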

How the results depend on the processing

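Gene length correction, the 1 surrogate variable, total gene reads and the joint omission of 3 libraries were chosen only after the data were seen, so they are tests, not predictions. Of 202 named calls none reversed, and 199 were kept with relative log expression scaling, 187 with the upper quartile, 194 with no filter, 153 of 154 with 100 reads in 3 libraries, 196 with DESeq2, 180 with voom, 129 of 190 with the compared groups alone, 190 with the replicate block, 202 without mitochondrial genes, 199 with unique reads, 191 with gene reads, 178 with RPKM, 193 with the length trend removed and 137 to 189 with 1 library left out. Depth limits rare transcripts, since 3 reads are 0.439 to 0.610 CPM. Counts below are genes called, and the cause of a move was not tested unless stated.

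DESeq2 called 56 genes for sapx tapx against wild type and 99 interactions, and RPKM gave 42 interactions. A fit of the compared groups alone, with fewer libraries to estimate the spread, called 3, 337 and 731 genes in sapx tapx, pgr5 and the triple mutant against wild type and gives no interaction. At a log2 fold change of at least 1, a stricter rule, 186, 539, 520 and 120 genes remained in pgr5 and the triple mutant against wild type and in the triple mutant against sapx tapx and pgr5, and overlaps of 121 and 133. An estimated correlation left 0, 1, 2, 2, 2 and 1 lists past the test.

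Replicate numbers do not pair the samples across all 4 genotypes, but same-number libraries went together between some genotypes. As a block the replicate numbers gave 29 calls for sapx tapx against wild type, 416 for the triple mutant against pgr5 and 50 interactions. The 18 pairs with the same number correlated at -0.663 to 0.612 (median -0.01, against 0.0633 for other pairs), and 7 of 12 libraries were best correlated with their own number. Between sapx tapx and the triple mutant, same-number pairs correlated at 0.372 to 0.612 and other pairs at -0.459 to 0.172. Between wild type and pgr5 these ranges were 0.188 to 0.440 and -0.332 to 0.152. A pairing between these genotypes, seen only afterwards, is not excluded, and the main fit does not use it. A candidate run term, which puts 1 pgr5 library with each other genotype and so leaves little of genotype to estimate, gave 1, 35, 47, 52, 11 and 0 calls, 4 lists for the interaction and 34 of 202 named calls. This assignment ranked 4 of 6 by mean correlation (-0.0399, range -0.171 to 0.212).

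With 1 surrogate variable there were 182, 1551, 2341, 603 and 318 calls for sapx tapx and pgr5 against wild type, the triple mutant against sapx tapx and pgr5, and the interaction. Leaving out replicate 2 of wild type, sapx tapx and the triple mutant together gave 773, 1470, 2989, 1091 and 325 for the 3 genotypes against wild type, the triple mutant against pgr5 and the interaction. By construction it leaves wild type with low and the other 2 with high rapid stress scores.

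Leaving out 1 library at a time gave 4 to 81, 210 to 660, 865 to 1853, 746 to 1523, 112 to 341 and 10 to 61 calls, and 8 to 10, 7 to 11, 7 to 13, 5 to 10, 7 to 9 and 5 to 9 lists. Directions turned in 10 cases, for lists that of camera, with the median given here. With 3 libraries left out these were MYB44 in pgr5 against wild type (0.79), the interaction of TCH4 (-3.36) and list medians of photoprotection in sapx tapx (0.0634) and jasmonate in pgr5 (-0.0146) and the interaction (-0.23). The others were glucosinolates with the run term (0.35) and jasmonate with the surrogate variable (-0.76) in the triple mutant against wild type, rapid stress genes against pgr5 with it (0.0651), and jasmonate in the interaction without wild type replicate 2 (-0.18) and in sapx tapx without wild type replicate 3 (-0.10). With 1 library left out the jasmonate median ranged from -0.112 to 1.56 in sapx tapx and from -0.18 to 1.3996 in the interaction.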

Other observations

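SAT32 (AT1G27760, chromosome 1, 9668584 to 9671616) and SEC10 (AT5G12370, chromosome 5, 4002775 to 4008804), chosen after their values were seen, were low in pgr5 alone. SAT32 stood at 152 ± 15.5, 146 ± 10.8, 44.5 ± 1.88 and 183 ± 25.8 CPM in wild type, sapx tapx, pgr5 and the triple mutant, with a log2 fold change of -1.77 ± 0.12 in pgr5 against wild type (adjusted p = 2.8e-05) and an interaction of 2.09 ± 0.16 (adjusted p = 0.000320). SEC10, which encodes a subunit of the exocyst complex, stood at 54.0 ± 0.485, 53.1 ± 1.19, 18.0 ± 0.833 and 44.1 ± 5.33 CPM, with -1.59 ± 0.10 in pgr5 and an interaction of 1.32 ± 0.14 (adjusted p = 0.00490). ZIP7 (AT2G04032, chromosome 2, 1289832 to 1291383), a metal transporter gene that lies within 1 Mb of PGR5 and was also chosen after its values were seen, had 161 and 151 reads in wild type and sapx tapx and 0 and 2 in pgr5 and the triple mutant. AT3G44970 (chromosome 3, 16432443 to 16434848), chosen in the same way, had 5, 3, 182 and 91 reads in the 4 genotypes.

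WRKY40, a stress transcription factor gene chosen after its values were seen, stood at 0.667, 58.2 and 0.315 CPM in wild type replicates 1 to 3. Beyond the comparisons given for them, no hypothesis was tested on these genes.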
